A study of Mus musculus with 14 samples.

How the data were processed

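RNA from microglia sorted out of mouse retina was sequenced as 14 libraries, each from 1 retina per the labels. Per the labels' protocols, retinas came from mice aged 12 weeks, and cells positive for Fcrls and CD11b and negative for Ly6c were collected after a Percoll gradient of 37% over 70%. A retina gave 100 to 600 cells, brought to 100 to 300 cells in 5 µl of lysis buffer. Mice carried APOE E3/E3 or APOE E4/E4 and received a sham or a microbead injection, giving 4 groups: APOE3 sham (n = 4), APOE4 sham (n = 4), APOE3 microbead (n = 3) and APOE4 microbead (n = 3). The labels do not say whether retinas came from separate animals, so every p-value measures the spread between these samples.

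Per the submitters' processing notes, reads were quantified with Salmon 1.4.0 against mm10, and R 4.0.3 with DESeq2 1.30.1 was used after that. The values used here are the deposited estimated counts per transcript of each library, with their effective lengths. The deposited series table holds TPM (transcript abundance scaled for length and depth) per gene and served as a check of the library labels: TPM recomputed from each library matched its own column within 1% for 99.2% to 99.4% of genes, and any other column for at most 2.51%. Of 116945 transcripts, 115945 were assigned to a gene with the GENCODE M21 annotation (GRCm38), giving 35449 genes, and 1000 had no gene there. Counts were summed per gene and rounded to whole numbers. Transcripts of near-identical genes share reads in such estimates, which concerns C4b and C4a, the class I H2 genes, Lilrb4a, the ribosomal protein genes with their pseudogenes and the mitochondrial genes with theirs. 9 genes, among them mt-Co2, mt-Co3 and mt-Atp6, had 0 reads in at least 2 libraries and at least 50 in at least 4, as can arise when near-identical transcripts take reads all or nothing, so values of the mitochondrial list are uncertain. The transcript set holds 1 Apoe gene, that of the mouse.

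Estimated reads per library ranged from 453429 to 730134. Genes were kept with filterByExpr of edgeR by group (minimum count 10, minimum total 15), which left 7605 genes of the 28158 with a read. Groups were compared with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with robust estimation and TMM scaling, in 1 model with 4 group means over all 14 libraries. The common biological coefficient of variation was 0.275 and the median prior degrees of freedom 18.1. The 5 comparisons were microbead against sham within each genotype, the genotype by treatment interaction, and APOE4 against APOE3 within sham and within microbead. Tests were two-sided. Unless another tool is named, each adjusted p for a gene is from this edgeR test with Benjamini-Hochberg adjustment over all genes tested, and genes are called at an adjusted p under 0.05. Fold changes are log2 with a standard error (SE) derived from the quasi-likelihood F statistic. Levels are TMM-normalised CPM (counts scaled to a common library size) with a standard deviation (SD). Intervals for ratios of read counts are exact at 95% and, like floors of 3 counts, cover counting error only.

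Gene lists, 34 in all, were fixed for microglial states, pathways and the other cell types of retina and blood. The 18 lists with at least 5 genes tested were compared with the other genes by camera (limma 3.58.1) with a preset correlation of 0.01. Camera was run again with an estimated correlation, but not in the other alternatives described below. The fry test, which asks whether genes of a list move on balance one way and does not compare them with other genes, was run beside it. List p-values are Benjamini-Hochberg adjusted over the lists of a comparison, and the p given for a list is that of camera with the preset correlation unless said otherwise. For all other lists only summed levels are given. Where a list's median, mean and test differed in sign, the median is given without the mean or the direction of the test. This concerned none of the lists called. Named genes follow a rule: up to 8 higher and 8 lower genes with the smallest adjusted p past the threshold, without predicted genes, pseudogenes and sex-linked genes; up to 4 members per list described with the smallest unadjusted p; and Apoe, Lgals3, Clec7a, Itgax, Spp1, P2ry12, Tmem119, Tgfbr1, Fcrls, Itgam and Ly6c2 where tested. Groups, tests, lists, the rule and the first set of alternatives were chosen before the data were examined.

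Alternatives changed 1 setting at a time, but in several the set of genes tested moved with it. The filter was applied again to the libraries kept, which left 5830 to 6481 genes with only the libraries compared, 7326 to 8316 with 1 library left out, 9048 without both APOE3 microbead 1 and 2, and 6338 when thinned, against 7605. DESeq2 also filters genes by their mean before adjustment, and adjusted over 4213 genes in APOE4, 1117 in the interaction and 2149 within the glaucoma model. The counts in all these differ in the genes tested too. The alternatives were DESeq2 (1.42.0) or limma-voom with quality weights as the test, DESeq2 size factors or library totals as the scaling, no filter or a stricter one, effective length offsets, a fit of only the libraries compared, a replicate block, the rod photoreceptor level as a covariate, no robust estimation, and each library left out in turn. Those added after seeing the data were a fit without the 12 genes at satellite repeats, the satellite read ratio or the monocyte marker level as a covariate, a fit without both APOE3 microbead libraries with the highest monocyte marker level, and counts thinned to 1 depth. The fit without both leaves 1 library in that group, whose spread is taken from the other groups. A value is called reversed only where it passed the threshold in either setting and its sign differs. An alternative with Xist as a covariate was not run, because Xist is not in the transcript set used, and 1 with the series table was not run, because that table holds TPM. The test was checked on simulated counts with the real library sizes, in which some genes were changed in 1 group. Before that change each gene had 1 mean over all libraries and 1 fitted spread for all 4 groups. For the comparison within APOE3 the test recovered 22.6%, 71.2% and 80.7% of genes changed 2-, 4- and 8-fold. Within APOE4 it recovered 14.3%, 68.9% and 92.9%. For the interaction it recovered 5.97%, 43.1% and 60.3%, so that most differences of 2-fold between the responses are not detectable at this size. Unchanged genes made up 1.83% of the simulated calls in APOE3, 8.15% in APOE4, 6.41% in the interaction, 8.21% between shams and 2.59% within the glaucoma model. In the list test camera called a list raised 2-fold and 0 of 16 others. Simulated genes were drawn independently of each other, so this does not check the list test where genes of a list are correlated. Nor does the simulation check either test where the spread differs between groups. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.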

Results

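Gene expression was measured in microglia, the resident macrophages of neural tissue, from retinas of APOE3 and APOE4 mice after a sham injection or an injection of microbeads, a glaucoma model in which beads obstruct fluid outflow and raise eye pressure. Libraries held 453429 to 730134 estimated reads. Of these, 38.6% to 65.3% fell on 12 genes at satellite repeats, which left 226122 to 446728 reads per library outside them. The satellite share was 54.6% ± 10.6 in APOE3 sham, 53.3% ± 13.6 in APOE3 microbead, 50.004% ± 5.14 in APOE4 sham and 55.8% ± 3.31 in APOE4 microbead (SD, n = 4, 3, 4 and 3). On the first principal component, with 17.1% of the variance, the APOE3 microbead libraries stood at 49.9, 33.9 and 19.1, the APOE4 microbead libraries at -2.75, 7.96 and 3.07, and all sham libraries between -19.1 and -8.16. Apoe itself had 7 reads over the APOE3 sham libraries, 27 over APOE3 microbead, 5 over APOE4 sham and 8 over APOE4 microbead. These correspond to 3.07 ± 3.52, 14.7 ± 2.13, 2.24 ± 2.69 and 4.92 ± 3.16 CPM (SD), too few reads to be tested, and a human sequence at the locus can be miscounted with the mouse transcript.

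The comparison of microbead with sham in APOE3 retinas asks how microglia of this genotype respond to the glaucoma model. Homeostatic microglial genes fell, and genes of disease-associated microglia, interferon response, antigen presentation and ribosomal proteins rose. P2ry12, a purinergic receptor typical of resting microglia (ENSMUSG00000036353, chromosome 3, 59216272 to 59262871), fell. It was at 898 ± 121 CPM in sham (SD, n = 4) and 254 ± 114 in microbead (SD, n = 3), with a log2 fold change of -1.82 ± 0.22 (SE, adjusted p = 6.03e-06). Hpgd, which inactivates prostaglandins (ENSMUSG00000031613, chromosome 8, 56294585 to 56321043), was at 100 ± 27.6 and 6.11 ± 1.39 CPM (-3.97 ± 0.38, adjusted p = 1.13e-07). Cd72, an inhibitory C-type lectin receptor (ENSMUSG00000028459, chromosome 4, 43446462 to 43454628), was at 25.0 ± 10.5 and 202 ± 15.3 CPM (2.99 ± 0.28, adjusted p = 1.13e-07). C4b, a complement component (ENSMUSG00000073418, chromosome 17, 34728380 to 34743882), was at 20.6 ± 13.5 and 542 ± 70.6 (4.72 ± 0.41, adjusted p = 5.05e-06).

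In all, 392 of 7605 genes were called in APOE3, 269 higher and 123 lower in microbead, 271 of them changed at least 2-fold. DESeq2 called 394, of which 362 were shared. Counts were lower with limma-voom (239), library totals as the scaling (149), length offsets (222) or only the libraries compared (227, over 6481 genes). The monocyte marker genes also stood higher: their summed level was 339 ± 214 CPM in APOE3 microbead (387, 526 and 105 in the 3 libraries) and 73.8 ± 28.6 in APOE3 sham. Of 18 lists, 13 passed with camera, 9 of them with an estimated correlation, and 11 passed with fry. The count of genes was 225 without APOE3 microbead 2, 37 without both APOE3 microbead 1 and 2 (33 of them shared), and 9 with the monocyte marker level as a covariate, the last 2 settings chosen after seeing the data. The fit without both rests on 1 APOE3 microbead library, with the spread taken from the other groups.

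**Figure D1:**
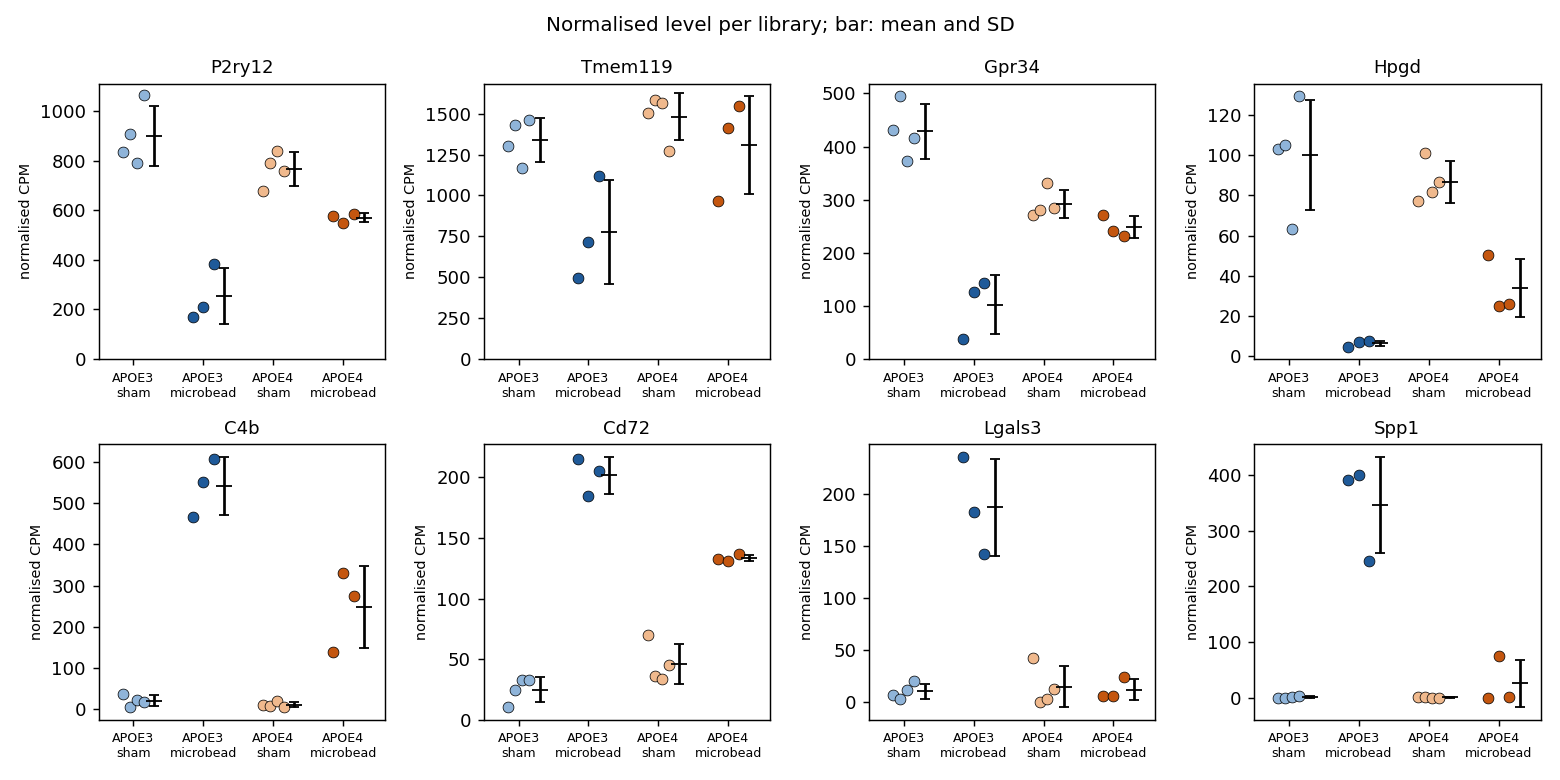
TMM-normalised CPM of P2ry12, Tmem119, Gpr34, Hpgd, C4b, Cd72, Lgals3 and Spp1 in each of the 14 libraries (points), by group, with the group mean and SD (bars). P2ry12 averaged 254 in APOE3 microbead and 570 in APOE4 microbead, and C4b stood above sham in both genotypes.

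Of 36 homeostatic genes tested, 16 fell and 0 rose in APOE3 (23 and 0 when adjusted over the list alone; list median -0.69, adjusted p = 1.74e-20). With an estimated correlation the adjusted p was 0.0237. Gpr34, a lysophosphatidylserine receptor, fell by 2.04 ± 0.27 on the log2 scale (adjusted p = 2.29e-05). The purinergic receptor P2ry13 changed by -1.45 ± 0.21 (adjusted p = 8.13e-05), and the fructose transporter Slc2a5 by -1.72 ± 0.27 (adjusted p = 0.000178). Tmem119, a microglial membrane protein, was at 1341 ± 135 and 777 ± 317 CPM (-0.79 ± 0.22, adjusted p = 0.0291). Its call was lost in 12 of 31 alternatives (adjusted p up to 0.864). These included the fits without APOE3 sham 1 (0.0559), sham 2 (0.0746), sham 4 (0.0633), microbead 1 (0.179) and microbead 2 (0.128). Tgfbr1, a receptor for TGF-beta, did not pass (-0.68 ± 0.21, adjusted p = 0.0507), nor did the sort marker Fcrls, at 222 and 220.4 CPM. Outside the list, Serpine2, a protease inhibitor (ENSMUSG00000026249, chromosome 1, 79794197 to 79861180), fell by 1.82 ± 0.24. Atp8a2, a phospholipid flippase, fell by 2.08 ± 0.31, Csmd3 by 2.41 ± 0.35 and Plxdc2 by 1.52 ± 0.24 (log2 ± SE, adjusted p 2.23e-05 to 0.000163 for these 4 genes).

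Disease-associated microglial genes rose in 23 of 35 (27 higher and 1 lower when adjusted over the list alone; median 1.52, adjusted p = 2.53e-31, 0.00523 as the adjusted p with an estimated correlation). Axl, a receptor for apoptotic cells, rose from 61.1 ± 22.2 to 310 ± 65.9 CPM (2.32 ± 0.24, adjusted p = 6.95e-07). Cd63, a tetraspanin of late endosomes, rose from 134 ± 19.7 to 451 ± 24.8 (1.76 ± 0.19, adjusted p = 1.30e-06). Fabp5, a fatty acid binding protein, rose by 4.12 ± 0.59 (adjusted p = 7.55e-05) and the inhibitory receptor Lilrb4a by 3.01 ± 0.43 (adjusted p = 0.000178). Lgals3, galectin-3 (ENSMUSG00000050335, chromosome 14, 47367751 to 47386160), rose from 10.7 ± 7.37 to 187 ± 46.5 CPM (4.01 ± 0.73, adjusted p = 0.00694). Spp1, osteopontin (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), rose from 1.41 ± 1.75 to 346 ± 86.5 (7.58 ± 1.10, 4 and 670 reads, adjusted p = 0.00251). Itgax, the CD11c integrin chain, rose by 2.67 ± 0.51 (adjusted p = 0.00341). Clec7a did not pass (0.45 ± 0.28, adjusted p = 0.514). Outside the list, Cd300lf, an inhibitory receptor, rose by 2.85 ± 0.34, the Src-family kinase Fgr by 3.75 ± 0.45, Plbd1 by 4.47 ± 0.57 and the adenosine receptor Adora1 by 3.26 ± 0.42 (adjusted p 4.59e-06 to 1.16e-05). In these same libraries the monocyte markers averaged 339 ± 214 CPM. Without both libraries richest in them the disease-associated median was 0.87 (adjusted p = 3.88e-17) and the homeostatic median -0.38 (adjusted p = 1.28e-07). With 1 APOE3 microbead library left, these p values do not hold its spread between replicates.

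Type I interferon genes rose in 12 of 35 (26 when adjusted over the list alone; median 1.35, adjusted p = 2.20e-22, 0.0326 as the adjusted p with an estimated correlation). Among them were Ifi207 (3.43 ± 0.51), the transcription factors Irf7 (2.63 ± 0.50) and Stat2 (1.15 ± 0.26), and the membrane protein Ifitm3 (3.29 ± 0.58). MHC and antigen presentation genes rose in 13 of 23 (15 over the list alone; median 0.84, adjusted p = 5.76e-17, 0.0355 as the adjusted p with an estimated correlation). The class I gene H2-D1 rose by 1.47 ± 0.20 and H2-K1 by 1.35 ± 0.22. The class II genes H2-Ab1 and H2-Aa rose by 3.05 ± 0.47 and 3.24 ± 0.53. H2-Ab1 was at 181 ± 61.2 CPM in sham and 1260, 2517 and 736 in the microbead libraries, which held 387, 526 and 105 CPM of monocyte markers. NF-kB targets and cytokines rose in 6 of 28 (7 over the list alone; median 0.67, adjusted p = 7.06e-08). They included the chemokines Cxcl16 (1.75 ± 0.23), Ccl5 (3.22 ± 0.57) and Ccl12 (2.47 ± 0.48). Il1b had 2 reads in sham and 46 in microbead, a ratio of 29.96 (95% counting interval 7.84 to 255). Complement genes rose in 4 of 10 (7 higher and 1 lower over the list alone; median 0.69, adjusted p = 2.57e-08), with C3 at 4.00 ± 0.80. Itgam, the CD11b chain used in the sort, was at 223 and 373 CPM (0.74 ± 0.22, adjusted p = 0.0442). That call was lost in 21 of 31 alternatives (adjusted p up to 0.448). They included the fits without any 1 of all libraries but APOE3 sham 4 and APOE4 microbead 1 (up to 0.159).

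Ribosomal protein mRNAs rose in 42 of 55 (50 higher and 1 lower when adjusted over the list alone; median 0.94, adjusted p = 4.58e-38, 0.0147 as the adjusted p with an estimated correlation). Rpl41 stood at 1.29 ± 0.21, Rpl19 at 1.14 ± 0.21, Rps27 at 1.07 ± 0.19 and Rpl6 at 1.03 ± 0.19. Glycolysis genes rose in 9 of 20 (10 higher and 1 lower over the list alone; median 0.69, adjusted p = 1.20e-07, 0.0204 with an estimated correlation). They included the enzymes Pgk1 (1.63 ± 0.29), Tpi1 (1.39 ± 0.22), Aldoa (1.09 ± 0.21) and Eno1 (0.97 ± 0.20). Nuclear oxidative phosphorylation genes rose in 2 of 59 (2 over the list alone; median 0.44, adjusted p = 3.36e-07). Lysosome and phagocytosis genes rose in 8 of 44 with 1 lower (13 and 1 over the list alone; median 0.30, adjusted p = 0.00023). With an estimated correlation these last 2 lists had an adjusted p = 0.113 each. Lysosomal members included the Fc receptor Fcgr2b (1.39 ± 0.22), the proton pump subunit Atp6v0c (1.09 ± 0.18), the sterol carrier Npc2 (0.98 ± 0.17) and, lower, the protease Ctsf (-1.22 ± 0.26). Rod photoreceptor genes had a median of -0.77 (0 of 20 called, adjusted p = 0.00928, 0.639 as the adjusted p with an estimated correlation). That call was lost without APOE3 sham 3 (0.366), sham 4 (0.143) or microbead 1 (0.256). Mitochondrially encoded mRNAs, whose counts are uncertain because mt-Co2 was at 0 in 8 libraries and at least 50 reads in 6, had a median of 0.57 (0 of 12 called, 1 over the list alone; adjusted p = 0.0163, 0.437 as the adjusted p with an estimated correlation). That call was lost without APOE3 sham 4 (0.0988) or microbead 1 (0.624). B cell genes fell in 1 of 5 (2 over the list alone; median -1.03, adjusted p = 0.0036), with Ighm at 267 and 104.5 CPM. Lists of cholesterol and lipid handling (median 0.17, adjusted p = 0.521), immediate-early response (0.02, adjusted p = 0.633), unfolded protein response (0.05, adjusted p = 0.668), cell cycle (0.16, adjusted p = 0.751) and TGF-beta signalling (-0.27, adjusted p = 0.751) did not pass. In the lipid list 2 genes rose and 2 fell (4 and 4 when adjusted over the list alone).

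**Figure D2:**
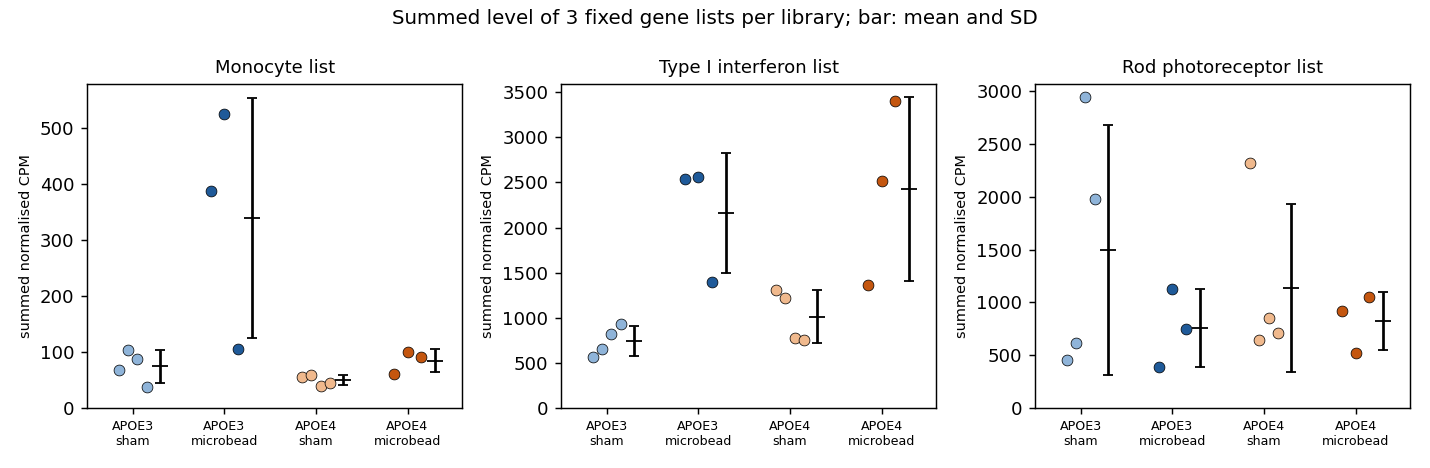
Summed TMM-normalised CPM of the monocyte, type I interferon and rod photoreceptor lists in each of the 14 libraries (points), by group, with mean and SD (bars). Monocyte markers stood at 387, 526 and 105 in the APOE3 microbead libraries and at 60.4, 99.7 and 91.6 in the APOE4 microbead libraries.

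The same comparison in APOE4 retinas gave a complement gene and interferon genes as the main rises. C4b rose from 10.6 ± 6.13 (SD, n = 4) to 248 ± 98.7 CPM (SD, n = 3), a log2 fold change of 4.52 ± 0.45 (SE, adjusted p = 0.000195). Cd72 rose from 46.4 ± 16.5 to 134 ± 2.73 CPM (1.52 ± 0.27, adjusted p = 0.0105). The antiviral gene Oas2 rose from 12.0 ± 8.75 to 144 ± 102 (3.57 ± 0.58, adjusted p = 0.0273) and Irf7 from 21.4 to 107 (2.33 ± 0.44, adjusted p = 0.0359). Zfp280d, a zinc finger gene (ENSMUSG00000038535, chromosome 9, 72274860 to 72363777), fell from 164 ± 18.8 to 38.1 ± 10.3 CPM (-2.11 ± 0.29, adjusted p = 0.000262). Hpgd fell from 86.7 ± 10.3 to 33.7 ± 14.4 (-1.38 ± 0.30, adjusted p = 0.0454). Others that rose were Adora1 (2.16 ± 0.39), Gcnt2 (1.71 ± 0.32), Cd300lf (1.87 ± 0.37), the Fc receptors Fcgr4 (1.76 ± 0.35) and Fcgr2b (1.04 ± 0.22), Itgam (1.01 ± 0.22) and progranulin, Grn (0.75 ± 0.16). P2ry12 was at 765 ± 67.8 and 570 ± 17.7 CPM (-0.42 ± 0.21, adjusted p = 0.775). Tmem119 was at 1482 and 1309 (-0.18 ± 0.21, adjusted p = 0.955) and Lgals3 at 14.96 and 12.3 (-0.24 ± 0.97, adjusted p = 0.996), none of them called. Itgax (0.80 ± 0.52), Clec7a (-0.61), Tgfbr1 (-0.25) and Fcrls (0.81 ± 0.25) did not pass either (adjusted p 0.298 to 0.921). Spp1 had 2 reads in sham and 46 in microbead, 45 of them in APOE4 microbead 2, a ratio of 30.9 (95% counting interval 8.08 to 263).

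In APOE4, 15 genes were called, 13 higher and 2 lower, with 494 at an unadjusted p under 0.05. DESeq2, adjusting over 4213 genes, called 34, among them all 15. C4b and Zfp280d kept their calls in all 31 alternatives, and each other gene named as changed lost its call in 8 to 19 of them. The count fell to 6 without APOE4 sham 2 and to 2 (C4b and Zfp280d) without APOE4 sham 3, without APOE4 sham 4, without APOE4 microbead 2 or without APOE4 microbead 3. Interferon genes passed in 2 of 35 (23 when adjusted over the list alone; median 1.22, adjusted p = 5.28e-31, 0.0479 as the adjusted p with an estimated correlation). Their summed level was 1013 ± 290 CPM in sham and 1366, 2512 and 3408 in the microbead libraries. Complement genes passed in 2 of 10 (2 over the list alone; median 0.37, adjusted p = 2.60e-08, 0.0479 with an estimated correlation). Lists of MHC genes (0 of 23, 4 over the list alone; median 0.34, adjusted p = 3.58e-06) and lysosome (2 of 44, 4 over the list alone; 0.29, adjusted p = 9.85e-06) rose with the preset correlation. So did disease-associated genes (0 of 35, 6 higher and 2 lower over the list alone; 0.43, adjusted p = 0.000103) and NF-kB targets (0 of 28, 3 over the list alone; 0.25, adjusted p = 0.000557). With an estimated correlation the adjusted p of these 4 lists was 0.350, 0.162, 0.285 and 0.219. In the disease-associated list, Cd63 (0.83 ± 0.19, adjusted p = 0.0746) and Ctsb (0.72, adjusted p = 0.0813) lay above sham without passing. Tyrobp, the signalling adaptor of TREM2, was at 957 and 597 CPM (-0.68, adjusted p = 0.102). The immediate-early and dissociation list fell (median -0.31, adjusted p = 0.00622, 0.722 as the adjusted p with an estimated correlation). That call was lost without APOE4 sham 3 (0.209), APOE4 microbead 1 (0.127) or APOE4 microbead 2 (0.119). The homeostatic list (-0.04, adjusted p = 0.123) and ribosomal proteins (0.10, adjusted p = 0.123) did not pass. Scaling by library totals moved the median of all genes by -0.23 in this comparison, -0.21 in the interaction and 0.16 between shams. There the homeostatic list of this comparison passed (-0.29, adjusted p = 0.0414) and the ribosomal median turned to -0.13. Monocyte markers were at 49.0 ± 9.19 in APOE4 sham and 83.9 ± 20.8 CPM in APOE4 microbead.

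The interaction asks whether the microbead effect differs between genotypes, as the effect in APOE4 minus that in APOE3. As lists, disease-associated and ribosomal genes responded less in APOE4 (adjusted p = 0.0451 each with an estimated correlation). Beside them the monocyte markers went from 73.8 ± 28.6 CPM in sham to 339 ± 214 in microbead in APOE3, and from 49.0 ± 9.19 to 83.9 ± 20.8 in APOE4. Ribosomal proteins already differed without glaucoma, at 7504 ± 996 CPM in APOE3 sham and 8952 ± 282 in APOE4 sham. The estimated correlation was not used with a library left out, so neither adjusted p of 0.0451 by camera was tried that way. Homeostatic genes were reduced less with the preset correlation but not with an estimated one (adjusted p = 0.122), and few single genes passed. Serpine2 differed by 1.91 ± 0.33 (SE, log2, adjusted p = 0.0155), Atp8a2 by 2.13 ± 0.41 (adjusted p = 0.0211), Hpgd by 2.59 ± 0.50 (adjusted p = 0.0211) and Gpr34 by 1.80 ± 0.36 (adjusted p = 0.0367). Fgr differed by -3.64 ± 0.65, Zfp280d by -2.12 ± 0.39 and Capg, an actin capping protein, by -2.72 ± 0.50 (adjusted p = 0.0155 each). These 7 were all the genes called, with 621 at an unadjusted p under 0.05. DESeq2, adjusting over 1117 genes, called 57, sharing 4, and limma-voom 5, sharing 4. Each of the 7 kept its sign and lost its call in 8 to 18 of 28 to 30 alternatives (adjusted p up to 0.656). The count was 30 without APOE3 microbead 3, 4 without APOE3 microbead 2 or without APOE4 microbead 3, and 3 without APOE3 sham 1 or without APOE3 microbead 1. It was 0 with edgeR without APOE4 sham 1, without APOE4 sham 2 or without APOE4 microbead 1 (549, 573 and 594 at an unadjusted p under 0.05). It was also 0 in edgeR with the monocyte marker level as a covariate (498).

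P2ry12 (1.395 ± 0.298) and Axl (-1.57 ± 0.34) missed the interaction threshold at an adjusted p = 0.0603 each. So did Lgals3 (-4.24 ± 1.24) at 0.293, Tmem119 (0.61 ± 0.30) at 0.620 and Spp1 (-2.97 ± 3.81) at 0.934. Itgax, Clec7a, Fcrls, Tgfbr1 and Itgam had an adjusted p from 0.441 to 0.922. By list, the ribosomal median was -0.83 (0 of 55 called, 1 higher and 33 lower when adjusted over the list alone; adjusted p = 1.13e-26, 0.0451 as the adjusted p with an estimated correlation). The disease-associated median was -1.29 (1 of 35, 16 over the list alone; adjusted p = 3.96e-15, 0.0451 with an estimated correlation). The homeostatic median was 0.68 (1 of 36, 17 over the list alone; adjusted p = 1.88e-14, 0.122 as the adjusted p with an estimated correlation). With the monocyte marker level as a covariate these 3 medians were -0.77, -0.91 and 0.49 (adjusted p = 3.54e-20, 5.30e-10 and 3.15e-06 at the preset correlation). Oxidative phosphorylation (-0.54, adjusted p = 3.54e-08), MHC (-0.60, adjusted p = 7.54e-06) and glycolysis genes (-0.44, adjusted p = 0.000845) also passed, at an adjusted p = 0.126, 0.350 and 0.125 with an estimated correlation. None of their genes was called over all genes, and 1, 3 and 7 were lower when adjusted over the list alone. B cell genes (1.07, adjusted p = 0.0183; 0.125 with an estimated correlation) lost that call without APOE3 microbead 1 (0.0702), APOE3 microbead 3 (0.0868) or APOE4 microbead 1 (0.0685). NF-kB targets (-0.31, adjusted p = 0.0329; 0.372 with an estimated correlation) lost it without APOE3 sham 1 (0.131), APOE3 sham 2 (0.112), APOE4 sham 3 (0.117), APOE3 microbead 2 (0.0533), APOE3 microbead 3 (0.0808) or APOE4 microbead 2 (0.143). The immediate-early list (-0.28, adjusted p = 0.016; 0.789 with an estimated correlation) lost it without APOE3 sham 1 or 2, APOE4 sham 3, APOE3 microbead 2 or 3, or APOE4 microbead 1 or 2 (up to 0.266). The interferon list did not pass (-0.25, adjusted p = 0.147).

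Across all 7605 genes the APOE3 and APOE4 effects had a Pearson correlation of 0.233 and a Spearman correlation of 0.173, with the same sign in 55.7%; genes are not independent replicates. Among the 392 genes called in APOE3, 83.7% had the same sign in APOE4 and 97.2% a smaller size, with a median absolute log2 change of 1.21 in APOE3 and 0.330 in APOE4. These genes were selected on their APOE3 effect, which favours a smaller size in APOE4. Over all 7605 genes 55.8% were smaller in APOE4, with medians of 0.333 and 0.277. Of the 13 genes higher in APOE4, 12 were also higher in APOE3, where independence gives 0.460, and 1 of the 2 lower genes was shared.

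**Figure D3:**
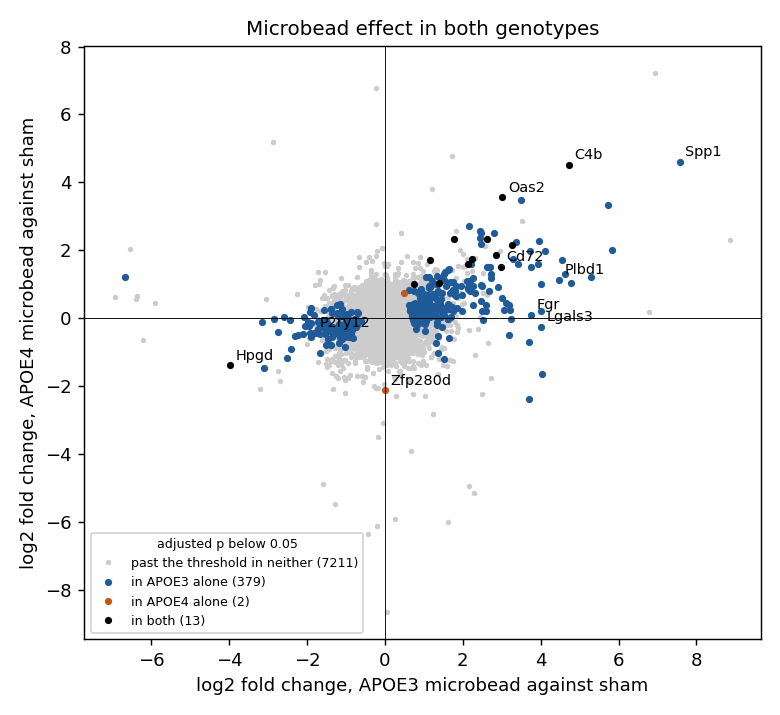
Log2 fold change of microbead against sham in APOE3 (horizontal) and APOE4 (vertical) for each of the 7605 genes tested, coloured by the genotype in which a gene was called. Of these, 379 were called in APOE3 alone, 2 in APOE4 alone and 13 in both.

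The comparison of the genotypes within the glaucoma model gives their difference in disease. As lists, glycolytic and disease-associated genes were lower in APOE4. Homeostatic genes were higher with the preset correlation, a call lost with an estimated correlation (adjusted p = 0.0534). P2ry12 was at 570 ± 17.7 CPM in APOE4 and 254 ± 114 in APOE3 (SD, n = 3 each; log2 fold change 1.16 ± 0.23 SE, adjusted p = 0.0101). The lectin Siglech was at 804 ± 71.0 and 358 ± 115 (1.17 ± 0.20, adjusted p = 0.00414) and Serpine2 at 225 and 67.8 (1.74 ± 0.26, adjusted p = 0.000816). Fth1, the ferritin heavy chain that stores iron, was at 942 ± 147 in APOE4 and 1927 ± 174 in APOE3 (-1.03 ± 0.19, adjusted p = 0.00561). Plbd1 was at 4.13 and 65.9 (-3.94 ± 0.61, adjusted p = 0.000958). Also higher in APOE4 were Atp8a2 (2.10 ± 0.32), Hpgd (2.37 ± 0.43), the transporter Slco2b1 (1.07 ± 0.20), the protease Ctsf (1.34 ± 0.27) and Sall1, a transcription factor of microglial identity (1.13 ± 0.23), with adjusted p 0.000958 to 0.0138. Also lower were Iqgap1 (-2.45 ± 0.39), Capg (-2.38 ± 0.38), Zfp280d (-1.74 ± 0.31), Ms4a7 (-2.06 ± 0.38), Pstpip1 (-2.12 ± 0.39) and thioredoxin, Txn1 (-2.37 ± 0.44), with adjusted p 0.00125 to 0.00556. H2-Ab1 was at 140 ± 54.5 CPM in APOE4 and 1504 ± 915 in APOE3 (-3.42 ± 0.54, adjusted p = 0.0138), beside 83.9 ± 20.8 and 339 ± 214 CPM of monocyte markers. Lgals3 (-3.88 ± 0.81, adjusted p = 0.077), Spp1 (-3.69 ± 0.85, adjusted p = 0.116), C4b (-1.12, adjusted p = 0.253) and Tmem119 (0.75 ± 0.23, adjusted p = 0.159) did not pass. Neither did Clec7a (-1.03, adjusted p = 0.164), Tgfbr1 (0.61, adjusted p = 0.278), Itgax (-1.19, adjusted p = 0.419), Fcrls (-0.28, adjusted p = 0.852) and Itgam (0.20, adjusted p = 0.899).

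Within the glaucoma model 44 genes were called, 17 higher and 27 lower in APOE4. DESeq2, adjusting over 2149 genes, called 73, sharing 30. The count was 121 without APOE3 microbead 3, 19 without APOE3 microbead 1, 16 without APOE3 microbead 2, 11 without APOE4 microbead 1 and 12 without APOE4 microbead 3. The P2ry12 call was lost without APOE3 microbead 1 (0.0752), APOE3 microbead 2 (0.0857), APOE4 microbead 1 (0.0573) or APOE4 microbead 3 (0.0742). Its adjusted p reached 0.913 among 30 alternatives. Serpine2, Atp8a2, Siglech, Iqgap1 and Capg kept their calls with each library left out. But nearly all 44 calls ended in the settings that address monocyte markers: the count was 1 with their level as a covariate and 2 without both APOE3 microbead 1 and 2, which leaves 1 library in that group. Plbd1 lost its call without APOE3 microbead 2 (0.0950), Hpgd and Slco2b1 without APOE4 microbead 1 (0.0834 and 0.0563), and Zfp280d without APOE4 microbead 3 (0.0636). Fth1 lost it without APOE4 microbead 1 or 3 (up to 0.0846), H2-Ab1 without APOE3 microbead 1 or APOE4 microbead 1 or 3 (up to 0.113), and Ctsf, Sall1, Ms4a7, Pstpip1 and Txn1 without 1 of APOE3 microbead 1 or 2 or APOE4 microbead 1 or 3 (up to 0.122). Disease-associated genes were lower (4 of 35, 23 when adjusted over the list alone; median -1.03, adjusted p = 4.48e-20, 0.0249 as the adjusted p with an estimated correlation). So were glycolysis genes (4 of 20, 9 over the list alone; -0.71, adjusted p = 1.29e-07, 0.0309 with an estimated correlation). Homeostatic genes were higher (6 of 36, 20 over the list alone; 0.59, adjusted p = 3.50e-19, 0.0534 as the adjusted p with an estimated correlation). Ribosomal proteins (-0.55, adjusted p = 4.89e-20), NF-kB targets (-0.43, adjusted p = 7.20e-06), MHC genes (-0.14, adjusted p = 2.15e-05) and oxidative phosphorylation (-0.47, adjusted p = 8.88e-09) were lower at the preset correlation. They had an adjusted p = 0.0561, 0.0581, 0.353 and 0.115 with an estimated correlation. Over all genes 0, 0, 3 and 0 of their members were called (34, 8, 5 and 0 lower when adjusted over the list alone). Immediate-early (-0.55, adjusted p = 0.00488), mitochondrial (-0.51, adjusted p = 0.00563) and B cell genes (0.69, adjusted p = 0.0456) also passed, at an adjusted p = 0.619, 0.431 and 0.156 with an estimated correlation. Immediate-early genes lost the call without APOE3 microbead 2 or 3 or APOE4 microbead 1 or 2 (adjusted p up to 0.159). Mitochondrial genes, with mt-Co2 at 214 reads in APOE3 microbead 1 and 0 in the other microbead libraries, lost it without APOE3 microbead 1 (0.536), and B cell genes without APOE3 microbead 1 or 3 or APOE4 microbead 1 or 2 (up to 0.224). The interferon list did not pass (0.26, adjusted p = 0.0966).

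Between the sham groups, which gives the genotype difference without glaucoma, microglial state genes showed no called change. P2ry12 (-0.23 ± 0.19, adjusted p = 0.962), Tmem119 (0.14 ± 0.20, adjusted p = 0.982), Lgals3 (0.37, adjusted p = 0.997) and Clec7a (0.04, adjusted p = 0.997) did not pass (n = 4 each). Tyrobp was at 568 CPM in APOE3 and 957 in APOE4 (0.75 ± 0.15, adjusted p = 0.152). The sort marker Fcrls was at 222 ± 59.9 and 104 ± 26.7 (-1.09 ± 0.24, adjusted p = 0.201) and Axl at 61.1 and 118 (0.93 ± 0.24, adjusted p = 0.536). The homeostatic median was 0.01 (adjusted p = 0.569) and the disease-associated median 0.09 (adjusted p = 0.334). Ribosomal proteins were higher in APOE4 (0 of 55 called, 52 of 55 positive; median 0.27, adjusted p = 8.22e-08), as were interferon genes (0 of 35; 0.45, adjusted p = 1.01e-05), each at an adjusted p = 0.888 with an estimated correlation and with 0 genes when adjusted over the list alone. A single gene was called, the processed pseudogene Gm5905 (-4.56 ± 0.81, adjusted p = 0.0458), named after its value was seen. The count was 0 without any 1 of the 8 sham libraries and 0 with limma-voom. There were 335 genes at an unadjusted p under 0.05 in edgeR, 386 in limma-voom and 258 in DESeq2, which called 1 other gene.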

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

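The fits with monocyte or satellite covariates, the fit without both APOE3 microbead libraries 1 and 2, the thinning to 1 depth, the test of 13 other cell types and the widened screen for single libraries were chosen only after the results were seen.

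The rise of disease-associated genes and fall of homeostatic genes in APOE3 microbead libraries may lie within the microglia or reflect other sorted cells. Recruited monocytes are a candidate source, although the gate was Ly6c-negative and Fcrls-positive. Of 17 marker genes, 2 averaged above 10 CPM in APOE3 sham. Ccr2 averaged 71.9 ± 50.9 CPM in APOE3 microbead against 12.1 ± 5.95 in sham, and Chil3 55.4 ± 90.9 against 1.61 ± 1.46. Whether microglia themselves raise these markers in the glaucoma model was not tested. With the monocyte marker level as a covariate the disease-associated median was 1.02 against 1.52 (adjusted p = 6.41e-17 by camera). Most of these markers have few reads and gauge such cells with error, and groups held 70.9% of the covariate's variance. The source of the part kept therefore stays open, like that of the part lost. A general admixture of other retinal and blood cells would raise their markers alike. Of 13 such lists, 0 stood higher in every APOE3 microbead than in every APOE3 sham library. Their log2 ratios ran from -1.13 for B cells to 0.73 for erythrocytes. The lists of monocytes, border-associated macrophages and dendritic cells were not among the 13, so admixture of those cells was not tested this way. With the satellite read ratio as a covariate the disease-associated median was 1.49 (adjusted p = 8.91e-31 by camera). What stays open is a state change of microglia under raised pressure, recruited cells for part or all of the pattern, or both.

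Ribosomal protein mRNAs rose in the same libraries by a median of 0.94, which might reflect how libraries captured short transcripts. Among 1000 random lists matched on length and expression the median was 0.17 and the highest 0.50, below 0.94 but not low enough to set this bias aside, so it and a ribosomal response cannot be told apart for part of the rise. Reads moved from pseudogenes to the genes would lower the pseudogenes. The summed level of the 190 pseudogenes with a ribosomal protein symbol went the other way, from 896.7 ± 91.9 to 1494 ± 179 CPM (log2 ratio 0.74). Pseudogenes with other symbols were left out, and reads shared between genes and pseudogenes could raise both. Sharing of reads is therefore not set aside. With the satellite read ratio as a covariate the ribosomal median was 0.95 (adjusted p = 5.48e-41). No biological cause of the ribosomal rise was tested.

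The larger count in APOE3 (392 genes) than in APOE4 (15) could come from depth, from 1 library or from monocyte-derived cells, beside genotype itself. At 1 depth the counts were 381 and 19. With 1 microbead library left out the lowest count in APOE3 was 225 and the highest in APOE4 17. These values argue against depth and against 1 library as the source. The counts also rest on a spread shared by the 4 groups. With only the libraries compared they were 227 in APOE3 (over 6481 genes) and 44 in APOE4 (over 6066), a smaller gap in the same direction. With the monocyte marker level as a covariate, counts were 9 and 8, as predicted if monocyte-derived cells made the difference, and the 392 genes had a median absolute log2 change of 1.02 (SE 0.43) against 1.21 (SE 0.27) before, all 392 with the same sign, and groups held 70.9% of the covariate's variance. Of 383 calls lost, the error widened by the larger factor in 277 (Lgals3, 4.01 ± 0.73 to 3.77 ± 1.15) and the change shrank by the larger in 106 (P2ry12, -1.82 ± 0.22 to -1.19 ± 0.28). Monocyte-derived cells in the APOE3 sort therefore stay open as a source of the difference in counts, as do a weaker microglial response in APOE4 and both together.

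Regrouping the same libraries tests whether chance gives such counts. For APOE3, 1 of 35 splits gave as many genes as the real 392 (highest other 54), and for APOE4 1 of 35 gave as many as 15 (highest other 4). In both that 1 was the real grouping, the smallest share that 35 splits can give. Each share lies under 0.05 taken alone, without adjustment over the comparisons. For the interaction 2 of 100 drawn splits gave at least 7 (highest other 17, by exchanging APOE4 sham 1 with APOE4 microbead 1, why was not tested). These exchange treatment within genotype, so they test for any microbead effect and not for equal effects. A draw added after seeing the data exchanged genotype within treatment, and 2 of 100 such splits gave at least 7 (highest other 8). That tests for any genotype effect in either treatment, so neither draw tests the interaction alone. Between shams 6 of 35 splits gave at least 1 gene (highest other 2), so chance is not excluded there. Within the glaucoma model the 10 splits are too few for a share under 0.05 (real 44, highest other 4).

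The test of the difference between genotypes singled out 7 genes, with log2 differences of 2.13 for Atp8a2, -2.72 for Capg, -3.64 for Fgr, 1.80 for Gpr34, 2.59 for Hpgd, 1.91 for Serpine2 and -2.12 for Zfp280d. It also singled out 9 lists by median difference: homeostatic (0.68), disease-associated (-1.29), MHC (-0.60), NF-kB targets (-0.31), glycolysis (-0.44), oxidative phosphorylation (-0.54), immediate-early (-0.28), ribosomal proteins (-0.83) and B cell (1.07). With an estimated correlation 7 of the 9 no longer passed, and the disease-associated and ribosomal lists did (adjusted p = 0.0451 each). Outside the comparisons, 2006 to 2695 reads per library (0.314% to 0.497%) lay in transcripts with no gene in the annotation, and they were not compared between groups.

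Among 480 groups of 4 libraries tested for a library far from the others, 19 were found, and chance gives about 1 in 20. In APOE3 sham, H2-K1 was at 259 CPM in library 1 (others 366 to 375) and Tgif1 at 18.9 (32.5 to 35.1). Oxidative phosphorylation genes were at 1754 CPM in library 2 (2251 to 2317), and mt-Co3 was at 100.2 there and 0 in the others. Over all 14 libraries mt-Co3 was at 0 in 7 and at least 50 reads in the other 7, so this value is uncertain. Library 3 had Top2a at 61.0 (6.002 to 12.0) and cell cycle genes at 671 (333 to 381). Library 4 had Mylip at 190 (97.6 to 105), Acvr1 at 27.6 (7.03 to 8.59) and retinal ganglion cell genes at 51.6 (65.0 to 66.8). In APOE4 sham, library 1 had Aldoa at 244 (154 to 168), Oas2 at 25.1 (7.11 to 8.28) and rod genes at 2324 (644 to 856). Library 2 had Txn1 at 4.97 (12.5 to 13.2). Library 3 had Soat1 at 81.8 (61.0 to 62.3), Klf2 at 55.1 (11.6 to 16.2), Lgmn at 1803 (1327 to 1376) and B cell genes at 363 (278 to 285). Library 4 had Ltc4s at 94.3 (70.0 to 72.9) and Itgb2 at 183 (253 to 260).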

How the results depend on the processing

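The 5 alternatives added after seeing the data were those without satellite-repeat genes, with the satellite ratio or the monocyte level as a covariate, without both APOE3 microbead 1 and 2, and thinned to 1 depth. The fit without both leaves 1 APOE3 microbead library, so the spread in that group is taken from the others. Of the results for single genes and lists, 14041 kept their side of the threshold, 683 were weaker, 269 stronger and 5 reversed. Direction was compared only where a result passed in either setting, so the 14041 include uncalled results whose sign may have changed. The mitochondrial list reversed with the monocyte covariate and without both libraries in the APOE3 comparison (adjusted p = 0.395 and 0.256) and within the glaucoma model (adjusted p = 0.682 and 0.220), and Hspa8 in APOE3 turned to -0.053 without both. The cause was not tested for these or for the counts below. For APOE3 (392) the count was 239 with limma-voom, 149 with library totals, 222 with length offsets, and 227 with only the libraries compared. It was 9 with the monocyte covariate, 37 without both libraries and 225 to 478 with 1 library left out. For APOE4 (15) it was 34 with DESeq2 (over 4213 genes), 24 with limma-voom, 3 with library totals, 53 with no filter, 5 with length offsets and 44 with only the libraries compared. It was 39 with the satellite covariate, 8 with the monocyte covariate, 26 without both and 2 to 17 with 1 left out. For the interaction (7) it was 57 with DESeq2 (over 1117), 2 with totals, 29 with no filter and 0 with length offsets (555 at an unadjusted p under 0.05 in edgeR). It was 22 with the satellite covariate, 0 with the monocyte covariate (498), 1 without both and 0 to 30 with 1 left out. Between shams (1) it was 12 with no filter, and 3 with the satellite covariate. It was 0 with limma-voom, totals, the stricter filter, length offsets, only the libraries compared, the rod covariate, no robust estimation, the monocyte covariate, without both, thinned, or any 1 sham library left out (266 to 482 at an unadjusted p under 0.05 in edgeR, 386 in limma-voom; DESeq2 called 1). Within the glaucoma model (44) it was 73 with DESeq2 (over 2149), 14 with totals, 111 with no filter, and 24 with length offsets. It was 1 with the monocyte covariate, 2 without both and 11 to 121 with 1 left out. Replicate numbers gave no sign of pairing: 0 of 19 pairs of libraries correlated above 0.1. The highest was 0.0985, for APOE3 sham 1 with APOE3 microbead 1. The value that true pairs would give is not known, so shared animals or days are not excluded. A block on replicate number gave 293, 5, 3, 0 and 33 genes in the order above (edgeR, 303 unadjusted between shams). A block within genotype gave 218, 5 and 0 (537 unadjusted) for APOE3, APOE4 and the interaction. It cannot give the comparisons between genotypes. Lists called in APOE4 (7) were 2 with an estimated correlation and 3 with fry, and in the interaction (9) 2 and 4. Within the glaucoma model (10) they were 2 and 6. Between shams (2) they were 0 and 0, with 4 for totals, 4 with the satellite covariate, 7 with the monocyte covariate and up to 4 with 1 library left out. The correlation of the APOE3 and APOE4 effects (0.233) was 0.199 with limma-voom, 0.0273 with no filter, 0.278 with the stricter filter, 0.182 with length offsets, 0.266 with the block and 0.194 with the block within genotype. It was 0.141 to 0.242 with 1 left out, 0.365 with the monocyte covariate and 0.142 without both. The APOE3 difference of Apoe, 11.6 CPM, became 26.2 without satellite-repeat genes, where the denominator is smaller. The value of 37.5 for the thinned setting divides reads before thinning by totals after it, so it is not a level at that depth. The fit of only the libraries compared equals the 14-library fit for the interaction, and the fits with no filter, length offsets or no robust estimation have no list test. At 453429 to 730134 reads per library, genes with few reads could not be tested, and Apoe and Ly6c2 were among them. For Apoe, depth is not separated from the lack of a human sequence in the transcript set, and for Ly6c2 not from the sort.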

Other observations

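The score of disease-associated minus interferon genes and the 4 other scores, with all their permutation tests, were chosen only after the results were seen.

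Markers of other cell types were low beside those of microglia. Homeostatic genes summed to 35361 ± 3281 CPM in APOE3 sham (SD, n = 4), 19346 ± 4897 in APOE3 microbead (n = 3), 35228 ± 1837 in APOE4 sham (n = 4) and 30422 ± 611 in APOE4 microbead (n = 3). Rod genes summed to 1497 ± 1181, 754 ± 371, 1134 ± 798 and 826 ± 276 CPM in the same order. B cell genes were at 333 ± 17.1, 152 ± 46.7, 302 ± 40.4 and 235 ± 34.6 CPM, and neutrophil genes at 333 ± 52.2, 253 ± 66.7, 335 ± 59.5 and 391 ± 63.4. Genes of Müller glia and astrocytes were at 218, 231, 221 and 231 CPM, and those of border-associated macrophages at 281 ± 48.5, 326 ± 120, 205 ± 27.4 and 206 ± 89.9. Endothelial and pericyte genes were at 62.4 ± 12.4 CPM in APOE3 sham and 87.5 ± 15.1 in APOE3 microbead. Dendritic cell genes were at 130 ± 10.3, 102 ± 36.9, 119 ± 19.2 and 81.3 ± 10.5 CPM. Other lists under 90 CPM in APOE3 sham were those of oligodendrocytes (77.2), monocytes (73.8), cones (76.5), ganglion cells (62.2), pigment epithelium (40.7), amacrine and horizontal cells (33.96), lens (32.0), bipolar cells (27.9), T and NK cells (22.2) and erythrocytes (7.53). The 4 sex-linked genes measured, Uty, Kdm5d, Ddx3y and Eif2s3y of the Y chromosome, summed to 183, 178, 186 and 175 CPM. Uty had at least 26 reads in every library.

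The mean log2 CPM of interferon genes was higher in microbead than in sham by 1.46 in APOE3 and 1.18 in APOE4, and that of disease-associated genes by 1.69 and 0.37. A hypothesis taken from these values is that the disease-associated part of the response is reduced more than the interferon part in APOE4, and the tests do not settle it. Permuting treatment within genotype, the genotype difference of the score (disease-associated minus interferon) was -1.05, with a one-sided exact permutation p = 0.00653 (8 of 1225 arrangements) and a two-sided p = 0.0114, or 0.0571 after Benjamini-Hochberg adjustment over 5 scores. That test asks whether there was any microbead effect, not whether effects were equal, and its side was the one already seen. Permuting genotype within treatment, which allows a microbead effect common to both genotypes, gave a two-sided exact permutation p = 0.151 (212 of 1400 arrangements, adjusted p = 0.189).

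The other scores had two-sided exact permutation p-values, with treatment permuted, of 0.0808 for disease-associated genes (-1.32), 0.784 for interferon genes (-0.27), 0.0473 for homeostatic genes (0.63) and 0.0473 for ribosomal proteins (-0.78), adjusted to 0.101, 0.784, 0.0789 and 0.0789. With genotype permuted they were 0.0243, 0.607, 0.0414 and 0.00143, adjusted to 0.0607, 0.607, 0.0690 and 0.00714. The value for ribosomal proteins is the smallest these arrangements can give (2 of 1400). Permuting genotype, here and for the score above, tests for any genotype effect in either treatment and not for unequal responses alone. Ribosomal proteins already summed to 7504 ± 996 CPM in APOE3 sham and 8952 ± 282 in APOE4 sham (SD, n = 4 each).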
